A study of Mus musculus with 4 samples.

How the data were processed

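RNA was measured in 4 libraries of sorted adult mouse neural stem cells. Per the labels' protocols, cells were isolated by flow cytometry from gfap:GFP mice of mixed CD1 and C57BL/6 background, RNA was extracted with a kit for very small samples, cDNA was made with the SMART-Seq v4 low-input kit, and paired-end reads were taken on an Illumina HiSeq. Per the submitters' processing notes, kallisto and sleuth were used with the mouse build mm10; their versions and the transcript release behind the index are not given in the sources used here. The deposited files give, per transcript, a length, an effective length, an estimated count and a TPM value.

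The estimated counts in the deposited files are those that kallisto assigns to each transcript by expectation maximization, so reads shared by several transcripts or near-identical genes are divided by estimate. TPM in the deposited files is the estimated count divided by effective length and scaled to the same fixed total over all transcripts of the index. It was recomputed from the deposited counts and lengths, and the largest difference in any library was 0.132 TPM. TPM is relative: a library in which a few genes take more RNA shows lower TPM for all others. The low-input kit amplifies cDNA and the labels name no molecular identifiers, so counts are not taken as independent molecules and limits cover counting error only.

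Transcript TPM was summed per gene with the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, matching Ensembl transcript identifiers without their version. Of 99567 transcripts 98294 matched (92612 with the same version) and gave 32564 genes; gene coordinates are from that annotation, counted from 1. The other 1273 transcripts were left out of tests. They held 0.530 to 0.619% of counts and 2.59 to 4.56% of TPM per library.

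The labels give 1 group, so no comparison between groups was made. The main test asked for each of 19914 genes with a count in any library whether the mean of log2(TPM + 1) differed from its value at 1 TPM (limma with a mean-variance trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). Calls were counted in 29 gene lists of 332 genes, fixed with the tests described in this paragraph before the data were examined. Of these genes Xist had no transcript in the index used here. For 12 pairs of lists, the difference of medians per library was tested by exact sign-flip permutation, which cannot go below p = 0.13 with 4 libraries. For 40 gene pairs the log2 ratio of TPM + 1 within libraries was tested with limma and adjusted over the pairs; the prior of that fit pooled the variance of all pairs completely, so it does not see that one pair varies more than another. Folds are on the log2(value + 1) scale. Spread was measured by the SD of log2(TPM + 1), the common dispersion of edgeR on counts rounded to whole numbers, and Spearman's rho. A count of 0 was given the level of 3 counts as its limit.

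Depth was 16978938 to 23727664 estimated counts per library. Tested on simulated counts with a dispersion of 0.1 over 19451 genes, limma called 86% of genes at 2 TPM and 100% of genes at 4 TPM as above 1 TPM, and 5.8% of 2000 genes set at 1 TPM in either direction. In the same simulation for 40 pairs, 80% of pairs with a ratio of 2 and 5% of pairs with a ratio of 1 were called. Every simulated gene had the same dispersion. In the data the edgeR coefficient of variation was 0.35 over genes of at least 1 TPM and 0.22 over genes of at least 10 TPM. Genes near 1 TPM may therefore vary more than was simulated, and the rates given for them may be too favourable.

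The genes named were chosen by a fixed rule. They were at most the 4 highest and 2 lowest of each list by mean TPM, all members of lists of 5 or fewer, genes of reported pairs past the threshold, any member of the clock, store-operated calcium and D-type cyclin lists, the 10 highest protein-coding genes that are neither mitochondrial nor ribosomal, and the 20 genes of largest SD among those of at least 10 TPM. Some genes that this rule selects are not reported here; they stay in the counts over lists and pairs but not in the totals of single results under the alternatives.

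Alternatives were a pseudocount of 0.1, a minimum mean of 5 estimated counts, a level of 5 TPM, TPM rescaled over nuclear protein-coding genes, scaling by TMM, edgeR's quasi-likelihood test with length offsets, CPM without length correction, the most abundant transcript per gene, list means, DESeq2 size factors, genes of at least 10 TPM, and each library left out in turn. Summing protein-coding transcripts only was added after the data were seen. Lists of further oligodendrocyte and microglia genes, of mRNAs known from myelin assembly sites, and of hormone, niche signal and neurotransmitter receptors were not among the fixed lists and were written later, before their values were read. Software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.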

Results

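Adult mouse neural stem cells, the cells of the ventricular wall that give rise to neurons in the adult brain, were profiled by RNA sequencing in 4 libraries of 1 group. The sample labels describe activated cells: they were sorted by flow cytometry from animals 3 months old with a GFP reporter for Gfap, they carried Gfap, Prom1 and Egfr, and they were untreated. The design text of the series instead describes quiescent cells taken after aCSF or miR204 antagomers were given into the ventricle. No sample label names either treatment, so the labels were followed and no groups were compared. The levels below are those of these 4 libraries whichever description applies. If the design text applied, every SD and p-value below could also hold a difference between treatments. The libraries held 22695719, 20526059, 16978938 and 23727664 estimated counts. Nothing in the labels says that the libraries came from separate animals, so every SD and p-value below measures the spread between these samples only, which may be technical.

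Across the transcriptome, transcripts of 12512 of 19914 genes tested were above 1 TPM, a unit of transcript abundance corrected for transcript length and library total, 4628 were below it and 2774 passed in neither direction (limma, adjusted p under 0.05, n = 4). The highest protein-coding level belonged to Apoe, the main lipid carrier of the brain, at 13786 ± 1313 TPM (SD, n = 4). It was followed by the protease inhibitor Cst3 at 12427 ± 1669 TPM and the predicted gene Gm20594 at 10763 ± 799 TPM. Gm20594 lies on chromosome 6, and whether it takes reads shared with other genes, mitochondrial ones included, was not tested. Also among the 10 highest were the prohormone-processing enzyme Cpe (6656 ± 1023 TPM), the ferritin subunit Fth1 (5547 ± 468 TPM), Clu (3683 ± 485 TPM), the creatine kinase Ckb (3528 ± 312 TPM), the metallothionein Mt1 (2993 ± 289 TPM) and Tmsb4x (2675 ± 312 TPM). Mitochondrially encoded genes, left out of that ranking, held between 13.49 and 18.38% of TPM. That share covers only genes on the mitochondrial chromosome, and reads that nuclear copies of them may hold are not in it.

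The first question was whether the libraries carried the RNA of the markers used for sorting and of stem cell states. Gfap, on chromosome 11 at 102887336 to 102900912 (mm10), stood at 149 ± 54.4 TPM, Egfr (chromosome 11, 16752203 to 16918158) at 89.7 ± 23.1 TPM and Prom1 (chromosome 5, 43993620 to 44102032) at 23.1 ± 7.01 TPM (SD, n = 4). All 15 genes of the neural stem core list were above 1 TPM, led by the glutamate transporter Slc1a3 at 1009 ± 145 TPM, Fabp7 at 365 ± 39.5 TPM, Sox9 at 329 ± 74.7 TPM and the Notch target Hes5 at 321 ± 67.4 TPM. Sox1 (12.8 ± 2.13 TPM) and Msi1 (8.30 ± 1.55 TPM) were the lowest of that list. All 20 genes known from quiescent stem cells or astrocytes were above 1 TPM, from Apoe, Cpe, Clu and Aldoc (2237 ± 306 TPM) down to the water channel Aqp4 at 66.4 ± 7.35 TPM and Bmpr1b at 22.8 ± 4.85 TPM. All 15 genes of activated stem cells or progenitors were above it as well, led by Gadd45g at 497 ± 101 TPM, Hes6 at 273 ± 20.2 TPM, Btg2 at 259 ± 117 TPM and the homeobox gene Dlx2 at 228 ± 43.0 TPM.

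Genes of activated cells stood lower than genes of quiescent cells or astrocytes in each of the 4 libraries. The difference of the list medians was -2.41 ± 0.31 on the log2 scale (SD, n = 4; exact sign-flip test, two-sided, p = 0.13, the smallest p that 4 libraries allow). It ranged from -3.00 to -2.15 over the alternative settings. The lists hold different genes and no other cell population was measured, so this difference does not tell whether the cells were activated or quiescent. Within libraries, Id4 was 2.27-fold higher than its relative Id3, Mycn was 4.56-fold higher than Myc, and Sox4 was 6.74-fold higher than Sox11, each in 4 of 4 libraries. Dlx2 was 1.55-fold higher than Dlx1 in 4 of 4 libraries, a call that was lost without library 3. Gfap was 1.62-fold higher than Egfr, but in only 3 of 4 libraries, and the call was lost without library 2 or library 3. The ratio of Egfr over Gfap turned to 0.18 on the log2 scale when counts were not corrected for transcript length.

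Ratios of this kind were tested for 40 gene pairs, most of them of related genes, of which 30 passed (limma, adjusted p under 0.05) and 26 of these had the same direction in all 4 libraries. The fit gave every pair the same pooled standard error, 0.24 on the log2 scale, so fold sizes and the number of libraries are given here in place of single p-values.

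**Figure D1:**
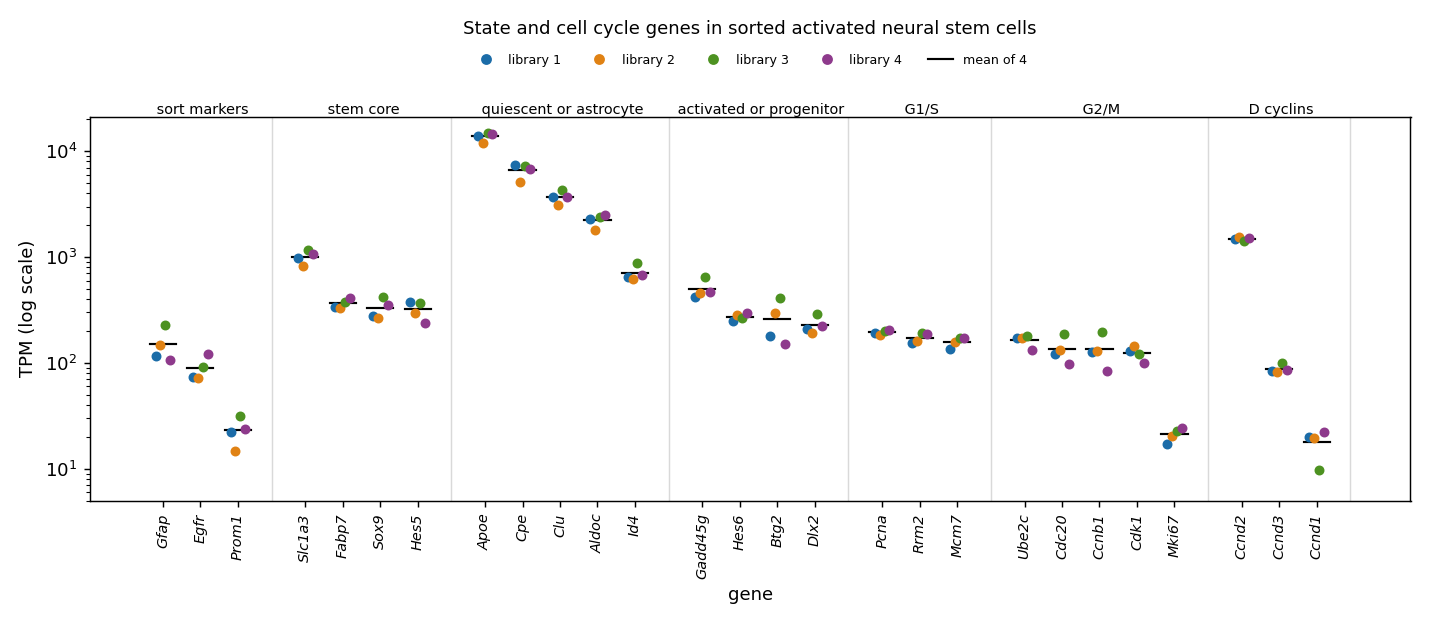
Levels of sort marker, stem cell state and cell cycle genes. The vertical axis gives TPM on a log scale, each point is 1 of 4 libraries, and the bar is their mean; quiescent or astrocyte genes such as Apoe (13786 TPM) stand highest, Ccnd2 (1488 TPM) stands above Ccnd1 (17.9 TPM), and Mki67 (21.2 TPM) is low among the G2/M genes shown.

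Cell cycle genes of both phases were detected throughout. All 18 G1/S genes were above 1 TPM, with the replication clamp Pcna at 195 ± 8.36 TPM, the ribonucleotide reductase subunit Rrm2 at 174 ± 18.8 TPM, Mcm7 at 158 ± 17.7 TPM and the histone mRNA-binding Slbp at 148 ± 9.23 TPM, and with Ccne1 lowest at 10.1 ± 4.83 TPM. All 18 G2/M genes were above 1 TPM, with Ube2c at 163 ± 21.9 TPM, Cdc20 at 135 ± 37.6 TPM, Ccnb1 at 135 ± 46.9 TPM and Cdk1 at 124 ± 18.5 TPM, and with Mki67 at 21.2 ± 2.98 TPM and Cenpe at 10.7 ± 2.72 TPM lowest. The G1/S median differed from the G2/M median by 0.08 ± 0.37 on the log2 scale, less than the spread between libraries (n = 4; exact sign-flip test, p = 0.75). That small difference changed sign when library 4 was left out, to -0.08, and when list means replaced medians, to -0.07, and it was 0.20 without library 3 and 0.37 without length correction.

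Among D-type cyclins, which start the cycle with their kinases, Ccnd2 reached 1488 ± 60.4 TPM (chromosome 6, 127125162 to 127152193), 82.2-fold above Ccnd1 at 17.9 ± 5.57 TPM and 16.7-fold above Ccnd3 at 88.1 ± 7.87 TPM, each in 4 of 4 libraries. Their partner Cdk4 (640 ± 30.8 TPM) stood 19.2-fold above Cdk6 (33.2 ± 9.05 TPM). Of the 12 cyclins, kinases and inhibitors listed, 11 were above 1 TPM and only Cdkn2a was below it (0.21 ± 0.25 TPM). Among the inhibitors above 1 TPM were Cdkn2d at 51.5 ± 7.75 TPM, Cdkn1a at 49.4 ± 10.1 TPM and Cdkn2b at 3.10 ± 1.57 TPM. The call of Cdkn2b was lost without library 1 (log2 difference from 1 TPM 0.78) or library 4 (0.79), and that of Cdkn2a with edgeR (-2.22); without library 2 the mean of Cdkn2a was 0.12 TPM. Cdkn1a was 1.92-fold higher than Cdkn1b in 4 of 4 libraries, a ratio that turned to -0.71 on the log2 scale without length correction and whose call was lost with the most abundant transcript only (0.43).

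Genes of regional identity, which mark where along the ventricle a stem cell lies, were above 1 TPM for 5 of 9 members and open for the other 4. Gsx2 (94.6 ± 25.4 TPM) stood highest, followed by Pax6 (38.8 ± 6.75 TPM), Nkx6-2 (36.1 ± 10.1 TPM) and Emx2 (15.2 ± 2.12 TPM). Gsx1 (1.06 ± 0.07 TPM) and Eomes (1.01 ± 1.11 TPM) passed in neither direction. The mean of Eomes was 0.58 TPM without library 2.

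Markers of other cell types of the region were read next. Oligodendrocyte genes were abundant: all 8 were above 1 TPM, led by the myelin gene Mbp at 1706 ± 215 TPM (chromosome 18, 82475146 to 82585637), with Mobp at 348 ± 39.7 TPM and Cnp at 335 ± 131 TPM. The leading transcript of Mobp was one annotated as subject to nonsense-mediated decay, and its log2 difference from 1 TPM was 7.44, but 4.82 with protein-coding transcripts only. All 10 microglia genes were above it, among them Ctss (58.4 ± 21.9 TPM), Csf1r (51.9 ± 30.1 TPM) and C1qa (51.1 ± 18.2 TPM). All 10 ependymal genes were above it, with Rarres2 at 256 ± 59.4 TPM, Tmem212 at 199 ± 61.2 TPM, Rsph1 at 135 ± 40.3 TPM and Dynlrb2 at 126 ± 46.3 TPM. The calls of the lowest ependymal members, Hydin (2.87 ± 1.45 TPM) and Dnah5 (2.51 ± 1.17 TPM), were both lost without library 2 (log2 difference from 1 TPM 0.74 and 0.61) or library 4 (0.69 and 0.60), and that of Dnah5 also without library 3 (0.75). That of Hydin was lost with protein-coding transcripts only as well (0.25). Of 14 neuroblast genes 13 were above 1 TPM, led by Cd24a (113 ± 29.3 TPM) and Tubb3 (97.9 ± 28.9 TPM), with Sp8 open at 1.02 ± 0.43 TPM. Of 10 genes of mature neurons 9 were above it, led by the striatal gene Ppp1r1b at 692 ± 52.7 TPM, Camk2a at 218 ± 39.6 TPM, Snap25 at 136 ± 27.9 TPM and Rbfox3 at 59.0 ± 8.53 TPM, while the cortical vesicular transporter Slc17a7 stayed open at 2.49 ± 1.57 TPM. Slc17a7 passed as above 1 TPM with at least 5 estimated counts (log2 difference 0.70), after rescaling over nuclear protein-coding genes (0.997), with edgeR (1.30) and without library 4 (0.93). The call of Drd1 (2.24 ± 0.96 TPM) was lost with a pseudocount of 0.1 (0.99) and without library 1 (0.57), library 3 (0.71) or library 4 (0.49).

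Lists of other cell types stood lower. Of 6 genes of oligodendrocyte precursors 5 were above 1 TPM, none of them beyond the 18.1 ± 8.39 TPM of Sox10, and Cspg4 was open at 3.15 ± 2.49 TPM. Cspg4 passed as above 1 TPM with at least 5 estimated counts (log2 difference 0.86), after rescaling over nuclear protein-coding genes (1.16), with edgeR (1.66) and without library 2 (1.14). Its mean was 2.04 TPM without library 4. Of 8 endothelial or mural genes only Pdgfrb (31.8 ± 8.59 TPM) and Pecam1 (3.87 ± 0.37 TPM) were above it, 4 were below it and the vascular cadherin Cdh5 and the channel Kcnj8 had no count in any library. Of the 4 below, the calls of Cldn5, Rgs5 and Ly6c1 were lost with edgeR (log2 difference -2.95, -2.28 and -1.40), and that of Ly6c1 also after rescaling (-0.49) and without library 3 or library 4 (-0.47 each). Cldn5 was named after its values were seen. Pecam1 rested on a retained-intron transcript and fell below 1 TPM when only protein-coding transcripts were summed. Of 6 choroid plexus genes 3 were above 1 TPM, led by Folr1 at 15.2 ± 7.03 TPM, and Ttr, an abundant transcript of that tissue, was at 0.49 ± 0.45 TPM. The call of Ttr as below 1 TPM was lost without library 2, library 3 or library 4 and with edgeR (log2 difference -0.50, -0.45, -0.30 and -1.03). It was also lost with a pseudocount of 0.1 (-1.37), with at least 5 estimated counts (-0.48) and after rescaling (-0.34). Its mean without library 1 was 0.29 TPM.

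The median of the stem core list was higher than that of endothelial or mural genes by 6.57 ± 0.38, of choroid plexus genes by 5.19 ± 0.35, of oligodendrocyte precursor genes by 4.11 ± 0.30, of neuroblast genes by 2.47 ± 0.50, of microglia genes by 1.49 ± 0.79 and of mature neuron genes by 1.45 ± 0.23 on the log2 scale, in 4 of 4 libraries each (n = 4; exact sign-flip test, p = 0.13 for each, the smallest possible). Against oligodendrocyte genes it differed by -0.58 ± 1.21 (p = 0.375, exact), against ependymal genes by 0.11 ± 0.51 (p = 0.625, exact) and against erythroid genes by 0.57 ± 2.38 (p = 0.75, exact), each with libraries on both sides of 0. The oligodendrocyte difference was 1.16 in library 1 against -1.55, -0.68 and -1.25 in libraries 2 to 4, ranged from -1.16 without library 1 to -0.26 without library 2, and turned to 0.57 with protein-coding transcripts only. The ependymal difference ranged from -0.06 without library 3 to 0.34 without library 2 and turned to -0.16 with the most abundant transcript only. The erythroid difference ranged from -0.48 without library 1 to 1.40 without library 4 and was 0.27 with the most abundant transcript only. With list means in place of medians the 3 differences were -0.33, 0.86 and 1.47. Without length correction the microglia, ependymal and erythroid differences were 2.45, 1.27 and 2.98. Each list holds different genes, so these differences do not measure shares of cell types.

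Hemoglobin RNA varied most of all lists. Hba-a1 ran to 428 ± 493 TPM, Hbb-bs to 281 ± 322 TPM, Hba-a2 to 151 ± 185 TPM and Hbb-bt to 11.6 ± 9.39 TPM, so that 4 of 5 erythroid genes were above 1 TPM and Alas2 was open at 1.77 ± 0.97 TPM. Alas2 passed as above it only after rescaling over nuclear protein-coding genes (log2 difference 0.68). Without library 4 the means of Hba-a1, Hbb-bs and Hba-a2 were 188, 126 and 60.6 TPM, and the call of Hbb-bt was lost without library 2, library 3 or library 4 (log2 difference 1.91, 1.81 and 1.54). Hba-a1 and Hba-a2 are near-identical copies whose reads the authors' quantification may have divided in either way.

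Immediate early and stress genes, which cells switch on quickly after a stimulus, stood high. All 14 were above 1 TPM, led by Fos at 2096 ± 831 TPM, Egr1 at 1192 ± 353 TPM, Jun at 801 ± 297 TPM and Jund at 682 ± 143 TPM, down to Socs3 at 88.5 ± 35.3 TPM and Fosb at 42.5 ± 15.9 TPM. The stem core median was lower than theirs in 4 of 4 libraries, by -1.36 ± 0.51 on the log2 scale (n = 4; exact sign-flip test, p = 0.13, the smallest possible). Relative to the mean of the other 3, the median immediate early gene differed by -0.45 in library 1, 0.38 in library 2, 0.75 in library 3 and -0.69 in library 4.

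The series title concerns the day and night cycle, and of the genes of the circadian clock 22 of 22 were above 1 TPM. The output factors Tef (219 ± 15.8 TPM) and Dbp (211 ± 38.2 TPM) and the repressor Nr1d1 (127 ± 18.6 TPM) stood highest. The activators Arntl and Clock were at 20.6 ± 2.35 and 7.91 ± 1.92 TPM, and the period genes Per3, Per2 and Per1 at 25.5 ± 9.81, 13.5 ± 1.62 and 9.55 ± 2.65 TPM. Cry2 was 3.51-fold higher than Cry1, Nr1d1 2.44-fold higher than Nr1d2, Npas2 2.36-fold higher than Clock and Bhlhe40 5.82-fold higher than Bhlhe41, each in 4 of 4 libraries; the Npas2 call was lost without length correction (log2 of Clock over Npas2 -0.33). Per3 was 1.73-fold higher than Per2 in 3 of 4 libraries, and the call was lost without library 3 (log2 of Per2 over Per3 -0.58), with the most abundant transcript only and with protein-coding transcripts only (-0.47 each). No sampling time is given in the labels used here. Neither melatonin receptor was detected: Mtnr1a (chromosome 8, 45069137 to 45088506) and Mtnr1b (chromosome 9, 15824528 to 15874556) had 0 estimated counts in every library, which allows, at 3 counts, up to 0.354 TPM for Mtnr1a and 0.293 TPM for Mtnr1b in the shallowest library. These limits cover counting error only.

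**Figure D2:**
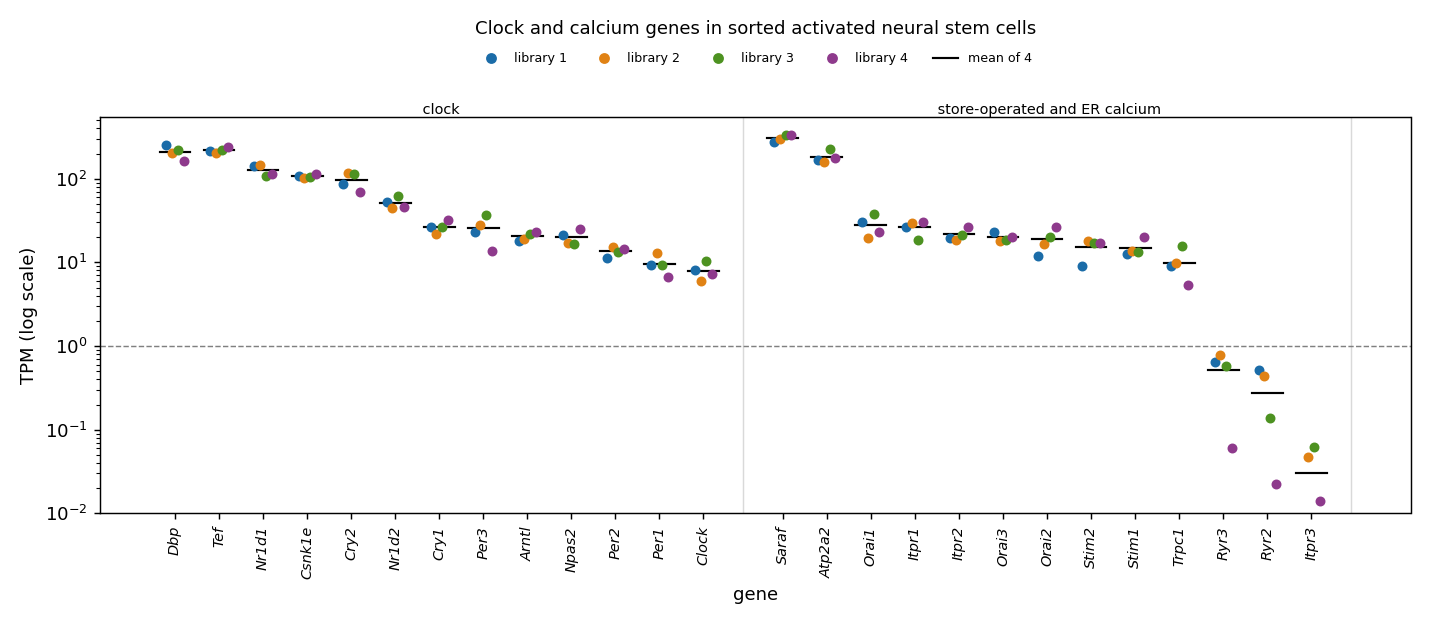
Levels of clock genes and of genes of store-operated and endoplasmic reticulum calcium handling. The vertical axis gives TPM on a log scale with 1 TPM dashed, each point is 1 of 4 libraries, and the bar is their mean; Itpr1 (26.3 TPM) and Itpr2 (21.5 TPM) stand above 1 TPM while Itpr3 (0.031 TPM, at 0 in library 1 and not drawn there), Ryr2 (0.28 TPM) and Ryr3 (0.52 TPM) stand below it.

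The title also concerns intracellular calcium, which leaves the endoplasmic reticulum through inositol trisphosphate and ryanodine receptors and is refilled by store-operated entry. Of 20 such genes 10 were above 1 TPM, 5 were below it and 5 were open. The entry regulator Saraf (311 ± 26.2 TPM) and the pump Atp2a2 (182 ± 30.3 TPM) were highest. The channels Orai1 (27.7 ± 8.12 TPM), Orai3 (20.02 ± 2.42 TPM) and Orai2 (18.9 ± 6.20 TPM) and the sensors Stim2 (15.2 ± 4.13 TPM) and Stim1 (14.9 ± 3.32 TPM) were all above 1 TPM. The release channels Itpr1 (26.3 ± 5.40 TPM) and Itpr2 (21.5 ± 3.66 TPM) exceeded Itpr3 (0.031 ± 0.029 TPM) 26.1-fold and 21.7-fold in 4 of 4 libraries, and Atp2a2 exceeded Atp2a3 (1.39 ± 1.12 TPM, 0.88 TPM without library 2) 82.4-fold. These folds are on the log2(TPM + 1) scale and understate ratios to genes under 1 TPM.

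Ryanodine receptors were low, with Ryr2 at 0.28 ± 0.23 TPM and Ryr3 at 0.52 ± 0.32 TPM below 1 TPM and Ryr1 open at 0.80 ± 0.95 TPM. Without library 4 the mean of Ryr1 was 0.33 TPM and it passed as below 1 TPM (log2 difference -0.60), as it did with protein-coding transcripts only (-0.94). Among the Trpc channels Trpc1 (9.96 ± 4.24 TPM) was above 1 TPM, and Trpc5 (0.28 ± 0.54 TPM) and Trpc6 (0.27 ± 0.39 TPM) were below it. The call of Ryr3 was lost without library 1, library 3 or library 4 (log2 difference -0.47, -0.45 and -0.26), with a pseudocount of 0.1 (-1.08), with at least 5 estimated counts (-0.42), after rescaling (-0.27) and with edgeR (-0.96). That of Trpc5 was lost without library 1, library 2 or library 3 (-0.63, -0.63 and -0.64) and with edgeR (-1.82). That of Trpc6 was lost with edgeR (-1.88). Means moved to 0.012 TPM for Trpc5 without library 4 and, without library 3, to 0.088 TPM for Trpc6 and 0.020 TPM for Itpr3. Orai1 over Orai2 was called at 1.46-fold from 3 of 4 libraries, was lost without library 1 or library 3 (log2 ratio 0.30 and 0.43), with a pseudocount of 0.1 (0.57) and with the most abundant transcript only (0.21). It turned to -0.52 on the log2 scale without length correction.

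Calcium channels of the plasma membrane that open with voltage were near the level tested: 4 of 10 were above 1 TPM, 3 below and 3 open. Cacna1s was highest at 8.18 ± 3.16 TPM, led by a processed transcript, and it fell below 1 TPM with protein-coding transcripts only. Cacna1a (4.20 ± 1.97 TPM) was next, and Cacna1g (0.20 ± 0.29 TPM) and Cacna1f (0.030 ± 0.043 TPM) were lowest. Only 2 of the 4 calls above 1 TPM held without library 1, without library 2, without library 3 or with protein-coding transcripts only. Of the 4, 3 held without library 4 or with a pseudocount of 0.1. Of the calls below, that of Cacna1g was lost with edgeR (log2 difference -2.34). That of Cacna1b, named after its values were seen, was lost with a pseudocount of 0.1 (-1.12), at least 5 estimated counts (-0.46), rescaling (-0.32) and edgeR (-1.08) and without library 1 (-0.35) or library 3 (-0.39). The mean of Cacna1g was 0.058 TPM without library 1 and that of Cacna1f 0.0091 TPM without library 4.

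Calcium extrusion and mitochondrial uptake genes were above 1 TPM for 8 of 12 members, below for 2 and open for 2. The uptake regulator Micu2 (44.9 ± 5.03 TPM) and the membrane pump Atp2b2 (41.2 ± 16.4 TPM) were among the highest, and Atp2b2 was 2.42-fold higher than Atp2b1 in 4 of 4 libraries, a call that was lost with the most abundant transcript of each gene only (log2 of Atp2b1 over Atp2b2 -0.26). Slc8a2 (0.35 ± 0.30 TPM) and Atp2b3 (0.27 ± 0.31 TPM) were below 1 TPM, and both calls were lost with edgeR (log2 difference -1.51 and -1.89); the mean of Slc8a2 was 0.21 TPM without library 1 and that of Atp2b3 0.17 TPM without library 2. Of 12 Gq and phospholipase C genes 10 were above 1 TPM, with Gna11 at 86.9 ± 15.1 TPM and Plcd4 at 45.3 ± 5.83 TPM, and Gna11 stood 3.46-fold above Gnaq in 4 of 4 libraries. Of 16 Gq-coupled receptors 10 were above 1 TPM, 2 below, 2 open and 2 without a count; the endothelin receptor Ednrb led at 181 ± 39.9 TPM, followed by the thrombin receptor F2r (39.9 ± 5.73 TPM), Lpar1 (25.8 ± 6.68 TPM) and Hrh1 (12.7 ± 2.39 TPM), and Chrm3 and Casr were the 2 at 0.

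All 19 calcium effector genes were above 1 TPM. Among the highest were Calm2 (935 ± 23.9 TPM), Calm3 (247 ± 26.0 TPM) and the calcineurin subunit Ppp3ca (186 ± 24.8 TPM). Ppp3ca was 11.5-fold higher than Ppp3cb, and Camk2b was 6.17-fold higher than Camk2d, each in 4 of 4 libraries. The levels of these and of the clock and calcium genes above are those of whole libraries. Those libraries also held RNA of mature neuron genes such as Camk2a (218 TPM) and of oligodendrocyte and ependymal genes. Which cells made the RNA was not measured.

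Trpm3, the gene that hosts miR204, was at 25.7 ± 5.69 TPM, and Meis2 (86.8 ± 5.71 TPM) stood 5.69-fold above Meis1 (14.5 ± 2.06 TPM) in 4 of 4 libraries; the 3 genes of that list were all above 1 TPM. The 4 Y-linked genes measured, Eif2s3y (38.0 ± 9.24 TPM), Ddx3y (27.1 ± 8.61 TPM), Uty (9.12 ± 3.91 TPM) and Kdm5d (5.80 ± 2.81 TPM), had RNA in every library, and Xist was not analysed here. The call of Kdm5d as above 1 TPM was lost with protein-coding transcripts only (log2 difference 0.41). The 10 housekeeping genes were all above 1 TPM, among them Ppia (2096 ± 153 TPM) and, as the lowest, Tbp (37.6 ± 7.90 TPM). With protein-coding transcripts only, the log2 difference from 1 TPM went from 10.03 to 4.33 for Ppia, from 3.48 to 1.49 for Itpr2, from 3.76 to 2.25 for Ddx3y, from 6.84 to 5.52 for Hba-a1, from 4.26 to 3.05 for Eif2s3y and from 8.32 to 7.17 for Cdk4. It fell less, but by over 1.5 times in level, for Nkx6-2 (3.36), Ppp1r1b (7.68), Calm3 (6.25), Cacna1a (0.61) and Stim2 (2.32), and all these calls held. The log2 ratio was 2.45 for Itpr2 over Itpr3, 3.11 for Cdk4 over Cdk6, -1.90 for Dlx1 over Dlx2 and 3.49 for Camk2b over Camk2d. This alternative was chosen after the data were seen. For all 29 lists, the counts above and below 1 TPM adjusted over the list alone equalled those adjusted over all genes tested. In sum over lists, 283 of 331 members were above 1 TPM, 19 below, 23 open and 6 without a count.

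The 4 libraries differed from one another in the RNA of particular cell types. Against the mean of the other 3, the median oligodendrocyte gene differed by -1.98 on the log2 scale in library 1, 0.70 in library 2, 0.37 in library 3 and 0.98 in library 4. The median microglia gene differed by -1.41, 0.13, 0.76 and 0.57, the median ependymal gene by -0.77, 0.51, -0.14 and 0.21, and the median erythroid gene by -3.65, 0.59, -0.06 and 3.10 in the same libraries. Neuroblast genes differed by 0.51, -0.17, -0.13 and -0.44 and genes of mature neurons by 0.39, -0.12, -0.29 and -0.04. The stem core differed by -0.04, -0.21, 0.32 and 0.07, clock genes by -0.01, -0.09, 0.13 and -0.15, and store-operated calcium genes by -0.16, -0.09, -0.00 and 0.09. The clock list mixes activators, repressors and output factors, so its median does not tell whether single clock genes were level between libraries. The mean of Per3, for instance, was 21.6 TPM without library 3 and 29.4 TPM without library 4. Mbp was at 1774, 1608, 1471 and 1969 TPM in libraries 1 to 4.

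**Figure D3:**
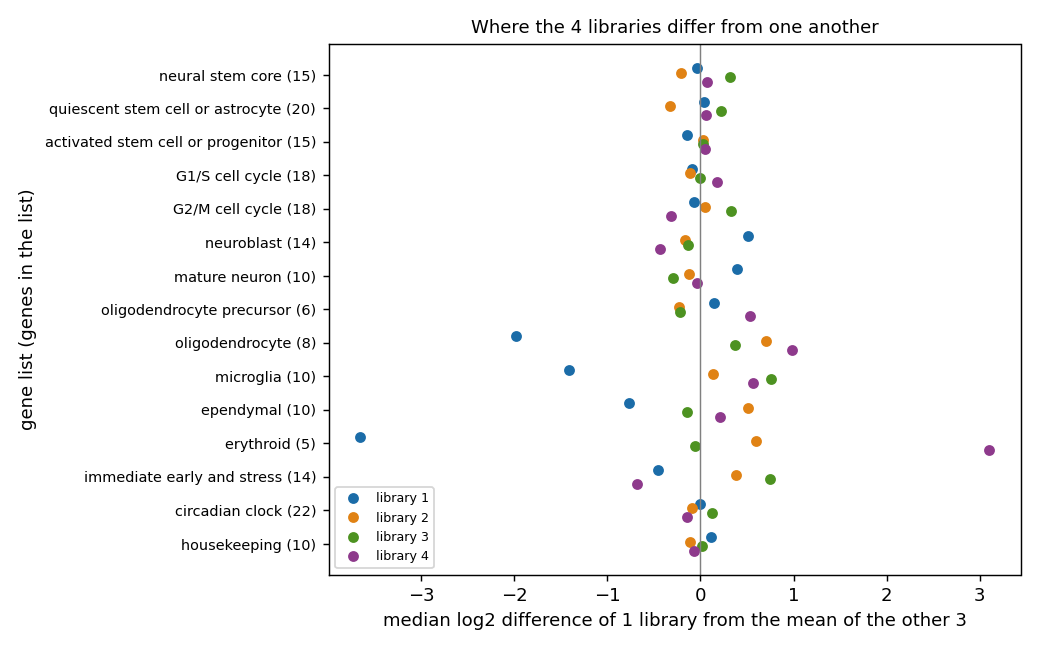
Deviation of each library from the other 3 by gene list. The horizontal axis gives the median log2 difference over the genes of a list, each row is a list with its number of genes, and each point is a library; erythroid genes spread from -3.65 to 3.10 and oligodendrocyte genes from -1.98 to 0.98, while housekeeping genes stay between -0.11 and 0.11.

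The 20 genes of at least 10 TPM with the largest SD included the hemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt and genes of myelinating cells, among them Mag (12.8, 174, 123 and 180 TPM in libraries 1 to 4), Ugt8a (1.13, 24.3, 26.3 and 14.7 TPM), Hapln2 (3.77, 47.4, 34.0 and 56.5 TPM) and Opalin (1.26, 22.5, 18.0 and 23.8 TPM). The largest SD of all was that of the pseudogene Hist1h2aj, at a mean of 34.4 estimated counts. Gm17604, Gm37419, Zfp969 and Gm32102 were also among the 20, at means of only 2.62, 6.25, 15.7 and 18.5 estimated counts. Pagr1a, Tada2b and the pseudogene Gm10925 were among them as well. Spp1 (2.28, 56.1, 0 and 3.50 TPM) and the antigen-presentation gene Cd74 (3.63, 31.2, 1.92 and 3.86 TPM) were highest in library 2. Over the 14087 genes of at least 1 TPM, the median SD was 0.30 on the log2 scale, the edgeR coefficient of variation was 0.35, and Spearman's rho across genes between pairs of libraries ran from 0.948 to 0.966, where genes are not independent replicates. Counts of any 2 libraries differed by a chi-square of 42.9 to 60.8 per degree of freedom, which is more than repeated sequencing of 1 library gives. That 2 libraries were prepared from the same RNA is not excluded.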

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

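The tests of neuronal genes and of depth in the next paragraph were chosen only after the result was seen; the others were set beforehand. In 18 of 234 sets of 4 values, 1 library lay far from the other 3 by Dixon's ratio of gap to range. Chance gives about 1 in 20 only for independent sets of normally spread values. These sets were not independent, since list medians and differences share genes with the single-gene sets. Cldn5 and Htr1a were flagged because only library 2 was above 0. The 18 therefore do not measure an excess over chance. Library 1 was the library set apart for the myelin genes Mag (12.8 TPM) and Opalin (1.26 TPM), for the microglia gene Ctss (25.8 TPM), and for the stem core minus microglia difference (2.67 on the log2 scale).

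Library 1 held less RNA of oligodendrocyte, microglia, erythroid and ependymal genes (-0.77 for the last, on the log2 scale) than the mean of the others. Lower depth and the scaling of TPM are argued against, since its estimated counts were 1.11 times the median of the others and its median nuclear protein-coding gene of at least 10 TPM differed by only -0.050 on the log2 scale. A higher share of stem cells with fewer cells of every other type alike would lower neuronal genes too. Neuroblast and mature neuron genes together instead differed by 0.46, and mature neuron genes alone by 0.39. This comparison was chosen after the values were seen, so it is no independent test. Fewer oligodendrocytes and microglia among the sorted cells may account for part of it. How far the gate on Gfap, Prom1 and Egfr removed these types was not measured, and all genes of their fixed lists were above 1 TPM. In library 1, 11 further oligodendrocyte genes differed by a median of -1.55, but 10 further microglia genes by -0.56, which lies between the bounds set beforehand. The most abundant of these genes was level for oligodendrocytes (Plekhb1 at 739, 586, 640 and 773 TPM) and slightly lower for microglia (Lgmn at 63.2, 82.0, 85.4 and 86.9 TPM). So this explanation stays open, and it would leave the ependymal and erythroid genes (-3.65 for the last) unexplained. Apart from these explanations by the mix of cells, no biological explanation was tested, because the labels give no group that parts the libraries.

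Mbp (0.087) and Mobp (-0.032, led by a transcript annotated for nonsense-mediated decay and not tested for its protein-coding part) were level in library 1 on the log2 scale, while the myelin genes Cnp, Mag and Opalin were lower there. RNA of myelin or of oligodendrocyte processes, carried over in every library apart from whole cells, may account for this: mRNAs known from myelin assembly sites differed by a median of -0.072, inside the bound set beforehand. Its 3 genes went apart, with Car2 at -1.34, Padi2 at -0.072 and Sh3gl3 at 0.11, and stem cells or astrocytes may express the last 2 themselves, so the median decides nothing. Transcription of Mbp and Mobp by the sorted cells themselves cannot be told apart from this source, since the value of 0.087 for Mbp does not tell which cell made the RNA and no single cells were measured. Whether Mbp and Mobp lie within reads shared with other genes was not tested.

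Other libraries far from the rest are given as values. The activated minus quiescent difference was -2.88 in library 1, and the median of endothelial or mural genes was 0.34 in library 2, both on the log2 scale. In library 1, Tubb3 was at 141 TPM and Stim2 at 9.08 TPM. In library 2, Cdkn1b was at 18.9 TPM, Cldn5 at 0.49 TPM, Gabrg1 at 41.5 TPM and Htr1a at 0.016 TPM. In library 4, Ube2c was at 131 TPM, Pax6 at 48.9 TPM, Trpc5 at 1.10 TPM, Rgs5 at 0.64 TPM, Eif2s3y at 51.8 TPM and Insr at 4.68 TPM.

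Transcripts outside the annotation, used in no comparison, held 3.78, 4.56, 2.59 and 2.78% of TPM in libraries 1 to 4 and are given here because they lie outside the main measurement. Most of it was 1 transcript, ENSMUST00000160554, at 29183, 35987, 18251 and 20038 TPM. Another, ENSMUST00000201828, held the same TPM as the pseudogenes Gm12895 and Gm12896 in every library (4332, 5187, 2650 and 3241 TPM). Both were chosen after their values were seen.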

How the results depend on the processing

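Genes above 1 TPM numbered between 11847 and 12795 over the alternatives that keep that level, and list members above it between 277 and 288. At a level of 5 TPM they were 9890 and 245. Pairs called numbered between 25 and 32, and each of these counts was within 1.5 times the main count. Genes below 1 TPM were more sensitive, at 949 with at least 5 estimated counts and 2300 after rescaling over nuclear protein-coding genes, 1866 with edgeR and 7528 at a level of 5 TPM, against 4628; they were 2773 with protein-coding transcripts only, an alternative chosen after the data were seen. List members below 1 TPM were 9 with at least 5 counts, 44 at 5 TPM and 4 with edgeR, against 19. The filter and the higher level set these counts by construction. Rescaling tested only the 16967 nuclear protein-coding genes, and the protein-coding alternative only genes with such transcripts detected, so both left genes out. How much of the change this makes, and the cause of the change with edgeR, was not tested.

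With protein-coding transcripts only, the log2 difference from 1 TPM turned to -0.70 for the level of Emx1, -0.61 for Pecam1, -0.50 for Trpc4 and -0.98 for Cacna1s, because the transcripts left out carried their signal. With the most abundant transcript only, the log2 ratio of Stim1/Stim2 turned to 1.11. Without length correction the log2 ratio was 0.18 for Egfr/Gfap, -0.52 for Orai1/Orai2, 0.61 for Orai2/Orai3, 0.86 for Ryr2/Ryr3, 2.37 for Atp2b1/Atp2b4, 0.86 for Csnk1d/Csnk1e, -1.52 for Rora/Rorb and -0.71 for Cdkn1a/Cdkn1b, which follows from transcript lengths. Genes named here for turning were chosen after their values were seen. Over single genes, 3080 results were the same, 70 lost their call and 27 gained one; over single pairs, 305 were the same, 22 lost their call and 6 gained one. The level of 5 TPM was not run for single genes.

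Of 12 list contrasts, 8 kept their direction under each alternative. G1/S minus G2/M turned to -0.069 with list means and ranged from -0.082 to 0.20 with 1 library left out. Stem core minus oligodendrocyte turned to 0.57 with protein-coding transcripts only and ranged from -1.16 to -0.26 with 1 library left out. Stem core minus ependymal turned to -0.16 with the most abundant transcript and ranged from -0.060 to 0.34 with 1 library left out. Stem core minus erythroid ranged from -0.48 to 1.40 with 1 library left out. The cause of these changes was not tested.

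The median SD was 0.32 with a pseudocount of 0.1 and 0.25 for genes of at least 10 TPM, and 0.27 to 0.29 with 1 library left out. The coefficient of variation was 0.22 for genes of at least 10 TPM and 0.31 to 0.38 with 1 library left out. The median Spearman's rho was 0.928 for genes of at least 10 TPM and 0.951 to 0.961 with 1 library left out. Depth limits what can be said of genes below 1 TPM, where a few counts decide the value. No paired analysis was possible because there is 1 group.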

Other observations

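Receptors outside the lists of the report were read from lists that were not among those fixed at the start but were written before their values were read, with the highest members named and, in 2 of the 3 lists, the lowest. Of 16 hormone receptors 11 were above 1 TPM, 3 below and 2 without a count. The thyroid hormone receptor Thra led at 238 ± 37.1 TPM (SD, n = 4), against 6.14 ± 1.40 TPM for Thrb, followed by the glucocorticoid receptor Nr3c1 at 52.5 ± 6.33 TPM, Insr at 19.5 ± 9.93 TPM and Rxra at 15.1 ± 4.44 TPM. Insr was led by a transcript annotated as a retained intron, and its level over protein-coding transcripts only is not given here. The estrogen receptor Esr1 and the vitamin D receptor Vdr had 0 estimated counts in every library. Of 20 receptors and mediators of niche signals 18 were above 1 TPM and 2 open, led by Fgfr2 at 100.2 ± 21.8 TPM, Plxnb2 at 91.4 ± 12.2 TPM, Smad4 at 86.5 ± 18.7 TPM and the integrin Itgb1 at 65.1 ± 7.49 TPM.

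Of 20 neurotransmitter receptor genes 12 were above 1 TPM, 3 below and 5 open. Subunits of the GABA-A receptor led, with Gabrb1 at 56.4 ± 12.2 TPM and Gabrg1 at 55.3 ± 9.31 TPM, followed by the AMPA receptor subunit Gria2 at 29.8 ± 4.96 TPM and Gabra4 at 26.2 ± 6.36 TPM. The leading transcript of Gria2 was one annotated as a retained intron, and its level over protein-coding transcripts only is not given here. The serotonin receptors Htr2c (0.16 ± 0.079 TPM) and Htr1a were lowest and below 1 TPM. Htr1a was at 0.016 TPM in library 2 and at 0 in the other 3. Sequence reads of these receptors come from the same libraries that hold the neuronal gene Snap25 at 136 ± 27.9 TPM.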
